A study of Xenopus laevis and Xenopus tropicalis with 96 samples.

How the data were processed

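Whole embryos were staged after Nieuwkoop and Faber and total RNA was measured on one-colour (Cy3) Agilent arrays, 48 per species. Per the labels' protocols, X. laevis was raised at 22 °C and X. tropicalis at 28 °C, an X. laevis sample came from 1 embryo and an X. tropicalis sample from 3 combined, 1 µg of total RNA was amplified by in vitro transcription with spike-in RNA of a kit with 10 mixtures, and 1.65 µg of labelled RNA was hybridised. Groups were species and stage, with the clutch letter of the labels as the replicate. The phases follow the labels: blastula (stages 2, 8 and 9), gastrula (10, 12 and 13), neurula (14, 16, 18 and 20) and tailbud (23, 25, 30 and 33). Stage 40 is outside that list and was kept as its own phase.

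The deposited scanner files hold intensities on a linear scale. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1, which subtracted background and spatial trend within each array, with no normalization between arrays. The flags for background, saturation and outlier spots are those the authors deposited with the intensities. The value tables of the authors' deposited series also hold intensities, and these equalled the processed signal of the same array within 0.1% for 46 of 48 X. laevis and all 48 X. tropicalis arrays. The 2 exceptions are the arrays of X. laevis clutch A at stage 40, whose columns carry each other's values and which were averaged. Each array had 43803 distinct probes for 16260 gene IDs, 11299 genes with 3 probes, 4945 with 2 and 16 with 1. None of the 16260 IDs was found in the reference list of gene names, so genes are given by their IDs. For that reason the 19 gene lists and the landmark genes written beforehand could not be used, and the species were matched by shared gene ID, not by symbol as planned.

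The processed signal was taken as log2 minus the log2 of the 75th percentile of its array. The 1417 control spots and flagged outlier spots were left out, with 0.04566% to 38.18% of the spots of an X. laevis array and 0.5936% to 13.14% of an X. tropicalis array flagged. A gene was represented by its brightest probe over all arrays of the species and kept if well above background on at least 2 arrays of a stage. Repeat arrays were averaged with the first array, so that n counts clutches. Spike-in scaling subtracted, in place of the 75th percentile, the mean over 4 spike-in RNAs of middle signal of the median log2 signal of their spots, 128 spots per array.

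Changes were tested on the log2 scale with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the packages jsonlite 2.0.0 and data.table, version 1.17.8, two-sided, in one fit over all groups of a species. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 log2 unit, and as variable over stages by the moderated F test with a range of stage means of at least 1 log2 unit. Differences between species were the interaction of species and stage in a joint fit. With 3 clutches in most groups, the p-values measure the spread between samples of different clutches at a stage. That spread was pooled over all groups of a species and not paired by clutch. In both species it also holds the spread between scans, and in X. laevis that between single embryos. The share of called genes that changed the same way in every clutch lay between 95.6% (X. tropicalis, stages 2 to 8) and 99.6% (X. tropicalis, stages 20 to 33). Over all genes tested it lay between 48% (X. laevis, stages 2 to 8) and 84.7% (X. tropicalis, stages 33 to 40, with 2 clutches at stage 40). The calls rest on the same clutches, so the higher share among them is no separate support. A gene not well above background on any array of the dimmer group has only a bound there. It is given as at least N-fold, the mean of the bright group against the mean of, per array, the higher of the lowest signal among probes well above background and the probe's own.

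For each step the gene with the largest rise and the gene with the largest fall in each species are named, by the fitted log2 change among called genes that had a value in every clutch measured at both stages and changed the same way in each, so that a called gene with a missing value can have a larger change. The rule fixed before the data were examined asked for 4 each way with a gene symbol, for members of gene lists, for landmarks and for species differences, and was reduced because the IDs carry no names. Profiles and stage similarity used log2 stage means of each gene centred within species, with the spread over the 9 pairs of an X. laevis and an X. tropicalis clutch as the error. These pairs cross the 3 clutches of each species. Each clutch enters several pairs, so the pairs are not independent replicates. Onset was the first stage past the midpoint between stage 2 and the later maximum, for genes that rose by at least 2 log2 units.

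The labels say that a letter marks a clutch, so samples of a letter are paired within a species. Deviations of the same clutch at the 2 stages of a step correlated across genes in X. laevis at 0.011 to 0.728 (14 of 15 above 0.1) and in X. tropicalis at 0.067 to 0.511 (13 of 14). No arrays held identical values. Each species used 12 slides of 4 arrays, and scans followed the clutches, with 3 in X. laevis, 1 per clutch. X. tropicalis had 4, of which the second held repeat arrays of clutch A with arrays of clutch C. Slides held 3 or 4 groups each and were entered as a random block. Within a scan each stage has 1 clutch, except for stage 8 in the second X. tropicalis scan (clutches A and C), no test was run within scans, and scans were entered as a block. The species were measured on separate slides and scans.

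The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, spike-in scaling, other filters on dim probes, the mean of a gene's probes, the series tables, first or repeat arrays alone, leaving out each clutch, the clutch, slide or scan as a block, fits of the 2 groups alone, separate fits per species, Spearman correlation and all measured genes. Normexp used median signals, as most files lack the mean signal. Those added later were flagged spots kept and 2 single arrays left out. The scripts were tested on simulated data with the real mean and spread of each gene, independent noise and few changed genes. The simulated data held no other stage changes and no correlation within a clutch or slide, so the results below are not error rates of the real data. For the step from stage 8 to 10 in X. laevis (15764 genes) the scripts recovered 49% of 100 genes changed by 1.5 log2 units and 90% of 100 changed by 3, with 7 false calls among 146. In X. tropicalis (15206 genes) it was 54% of 50 and 87% of 100, with 0 false calls among 114. For the difference between species at that step (14990 genes) it was 28% of 50 genes that differed by 1.5. Figures were drawn with matplotlib 3.10.9.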

Results

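Gene expression was measured through the development of wild-type embryos of 2 clawed frogs, Xenopus laevis and Xenopus tropicalis. X. laevis is an allotetraploid, which carries many genes as a pair of homeologous copies, and X. tropicalis is a diploid. Each species was sampled at 15 Nieuwkoop-Faber stages, from the cleaving egg at stage 2 to the swimming larva at stage 40, and each stage was sampled in 3 clutches, A, B and C, which are the replicates. Stage 40 of X. tropicalis was measured in 2 clutches. The same letter marks the same clutch across the stages of a species, and the letters of the 2 species are unrelated. There were 48 one-colour arrays per species. Of these, 2 X. tropicalis arrays were labelled as an env_control of stage 10, a term that the labels do not explain, and 5 arrays repeated a clutch and stage. Each array carried probes for 16260 Ensembl gene IDs of X. tropicalis, with different probes on the arrays of the 2 species, so that changes over stages, and not levels, were compared between species. The IDs are not paired with gene names in the files, and the homeologous copies of X. laevis are not told apart by them. The 75th percentile of the array signal lay between 11620 and 52310 in X. laevis and between 14590 and 40690 in X. tropicalis, and a median of 84.3% and 77.29% of the probes were well above background. The number of arrays limits the precision. After dim genes were removed, 15764 genes remained in X. laevis, 15206 in X. tropicalis and 14990 in both.

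Most genes changed during development in both species. In X. laevis 12323 of 15764 genes (78.2%) varied over the 15 stages by at least 2-fold and passed the moderated F test, with a median range of 2.69 log2 units between the highest and lowest stage. In X. tropicalis 13802 of 15206 genes (90.8%) did, with a median range of 3.17 log2 units. The genes fell into groups by the phase of their highest stage. At blastula stages, when maternal transcripts make up most of the RNA, 2577 variable genes (20.9%) had their highest signal in X. laevis and 2976 (21.6%) in X. tropicalis. The gastrula held the peak of 2025 genes (16.4%) in X. laevis and 2434 (17.6%) in X. tropicalis. The neurula held that of 2012 (16.3%) and 2587 (18.7%), and the tailbud stages that of 2169 (17.6%) and 2138 (15.5%). Stage 40, a single stage, held the highest signal of the most genes of any phase, 3540 (28.7%) in X. laevis and 3667 (26.6%) in X. tropicalis. These shares depended on the scaling. With the arrays set by their spike-in RNA, 63.95% of the variable genes of X. laevis and 65.15% of those of X. tropicalis peaked in the tailbud phase, and with quantile normalization 37.74% and 35.1% peaked in the blastula.

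The phase of the peak was shared by many genes of the 2 species. Of 11235 matched genes that varied in both, 6067 (54%) had their highest stage in the same phase, against 20.9% for independent assignments. Of the genes that peaked at stage 40 in X. laevis, 63.8% did so in X. tropicalis, and of those that peaked in the blastula of X. laevis 60.8% did so. The share was 48.4% for the gastrula, 47% for the neurula and 41.8% for the tailbud stages. A further 3058 genes (27.2%) peaked in neighbouring phases. A later phase in X. laevis was found for 25.4% of the genes and a later phase in X. tropicalis for 20.6%. At the other extreme, 261 genes peaked in the blastula of X. laevis and at stage 40 of X. tropicalis, and 211 the other way round, where independence would give 663.9 and 694.7.

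Few genes changed between stages 2 and 8, before and at the onset of transcription by the embryo. In X. laevis 155 genes were called, 132 higher and 23 lower at stage 8, and in X. tropicalis 776, 712 higher and 64 lower. Here and in the later steps, the largest rises and falls are those among called genes with a value in every clutch measured at both stages. They are ranked by the fitted change, so the rank of a gene given as at least N-fold rests on signal not well above background. Changes given for the same gene in the other species are fitted changes that were not checked against background. Such a change can exceed the largest one named, where a clutch lacked a value or went the other way. The largest rise in X. laevis was that of ENSXETG00000019913, 80.9-fold (6.34 ± 0.36 log2 units, SE, n = 3 clutches per stage, limma adjusted p = 4.68e-14). The same gene rose in X. tropicalis by 3.63 log2 units, and the difference between species did not pass the test (adjusted p = 0.0724). ENSXETG00000026798 had the largest rise in X. tropicalis, 686-fold (9.42 ± 0.36, n = 3, limma adjusted p = 1.41e-18), with 1 of 3 stage 2 arrays well above background. It rose by 3.57 log2 units in X. laevis, less than in X. tropicalis (adjusted p of the difference 1.49e-10). The falls were small, 5.32-fold for ENSXETG00000002427 in X. laevis (well above background on 1 of 3 arrays at stage 8) and 9.38-fold for ENSXETG00000016586 in X. tropicalis. The call of ENSXETG00000002427 ended without clutch A or C (adjusted p = 0.127 and 0.434) and with the normexp background (0.464), and that of ENSXETG00000016586 without clutch A or B (0.0511 and 0.14) and with quantile normalization (0.0545), and both ended, with that of ENSXETG00000019913, when stages 2 and 8 alone were fitted (0.647, 0.223 and 0.16). With the clutch as a block 252 X. laevis genes were called. Without clutch A 38 were called, without clutch C 25, with spike-in scaling 34 and from the 2 stages alone 0. In the fit over all stages 1301 X. laevis genes (8.3%) and 3243 X. tropicalis genes (21.3%) had an unadjusted limma p under 0.05. In X. tropicalis 366 genes were called without clutch B and 85 from the 2 stages alone, spike-in scaling called 2048 higher and 2 lower, and quantile normalization 443 higher and 112 lower.

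Between stages 8 and 10, from the mid-blastula transition to the start of gastrulation, rises outnumbered falls in both species. X. laevis had 1458 called genes, 1029 higher and 429 lower at stage 10, and X. tropicalis 4098, 2981 higher and 1117 lower. Among the called genes alone, the median rise was 2.58 log2 units in X. laevis and 1.80 in X. tropicalis, and 283 and 346 genes rose by at least 4 log2 units. No X. laevis gene and 1 X. tropicalis gene fell by as much. ENSXETG00000019924 led the X. laevis rises at 1350-fold (10.39 ± 0.61 log2 units, SE, n = 3, limma adjusted p = 3.18e-15), with 2 of 3 stage 8 arrays well above background, and it rose by 6.19 in X. tropicalis (adjusted p of the difference 0.000224). ENSXETG00000001339 led in X. tropicalis, at least 1120-fold higher at stage 10 (n = 3, limma adjusted p = 5.9e-20), since it was not well above background at stage 8, and it rose by 9.70 log2 units in X. laevis. The largest falls were 11.8-fold for ENSXETG00000024589 in X. laevis, which fell by 2.63 log2 units in X. tropicalis, and 16.4-fold for ENSXETG00000016286 in X. tropicalis (well above background on 1 of 3 arrays at stage 10). The direction of the balance depended on the scaling. Spike-in scaling, which moved the median change of all genes from 0.18 to -0.41 log2 units in X. laevis and from 0.37 to -1.30 in X. tropicalis, gave 539 higher and 686 lower genes and 592 higher and 7841 lower genes, and quantile normalization 825 and 623, and 1601 and 1364. Without clutch C 916 X. laevis genes were called and from the 2 stages alone 802, and the normexp background left 2547 in X. tropicalis.

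The step from stage 10 to stage 20, across gastrulation and neurulation, held the most changes of the 5 steps with 75th-percentile scaling. In X. laevis 6216 genes (39.4%) were called, 3920 higher and 2296 lower at stage 20, and in X. tropicalis 7066 (46.5%), 3950 higher and 3116 lower. Rises of at least 4 log2 units were seen for 775 and 1030 genes and falls of that size for 121 and 223. ENSXETG00000008317 rose 1930-fold in X. laevis (10.92 ± 0.58 log2 units, SE, n = 3, limma adjusted p = 2.92e-16) and by 8.55 log2 units in X. tropicalis (adjusted p of the difference 0.0145). ENSXETG00000024534 was at least 2070-fold higher at stage 20 in X. tropicalis (n = 3, limma adjusted p = 1.38e-15) and rose by 11.85 log2 units in X. laevis (adjusted p of the difference 0.426). The genes with the largest falls fell in both species. ENSXETG00000025923 fell 274-fold in X. laevis and fell by 7.29 log2 units in X. tropicalis, and ENSXETG00000026217 fell 319-fold in X. tropicalis (well above background on 2 of 3 arrays at stage 20) and fell by 7.24 log2 units in X. laevis. Neither difference between species in the falls passed the test (adjusted p = 0.542 and 0.576). Spike-in scaling gave 4549 higher and 1201 lower genes in X. laevis and 5322 and 1373 in X. tropicalis, where the 6695 genes were fewer than the 8433 from stage 8 to 10 and the 7320 from stage 20 to 33, and quantile normalization 2740 and 3236, and 3129 and 4140.

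From stage 20 to stage 33, as the tailbud embryo forms its organs, 3587 genes were called in X. laevis, 2136 higher and 1451 lower, and 4813 in X. tropicalis, 3042 higher and 1771 lower. ENSXETG00000024628 rose 3110-fold in X. laevis (11.60 ± 0.71 log2 units, SE, n = 3, limma adjusted p = 1.07e-13), with 2 of 3 stage 20 arrays well above background, and less in X. tropicalis, by 6.10 log2 units (adjusted p of the difference 0.00101). ENSXETG00000026769 was at least 450-fold higher at stage 33 in X. tropicalis (n = 3, limma adjusted p = 1.15e-11), and its change in X. laevis was 10.53 log2 units. ENSXETG00000015923 fell 88.4-fold in X. laevis and, more steeply, fell by 11.10 log2 units in X. tropicalis (adjusted p of the difference 0.00088). ENSXETG00000023814 fell 944-fold in X. tropicalis (a change of -9.88 log2 units, well above background on 2 of 3 arrays at stage 33) and, less steeply, fell by 6.08 log2 units in X. laevis (adjusted p of the difference 4.64e-07). Spike-in scaling gave 4770 higher and 183 lower genes in X. laevis and 7018 and 302 in X. tropicalis, and quantile normalization 1987 and 2581, and 2602 and 2926.

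From stage 33 to stage 40 the changes were fewer, and most were rises. In X. laevis 1398 genes were called, 1059 higher and 339 lower at stage 40, and in X. tropicalis, with 2 clutches at stage 40, 1776, 1318 higher and 458 lower. ENSXETG00000009708 was at least 73.4-fold higher at stage 40 in X. laevis (n = 3, limma adjusted p = 3.1e-10), and its change in X. tropicalis, 1.81 ± 1.07 log2 units, did not pass the test (adjusted p = 0.256). ENSXETG00000025158 was at least 171-fold higher in X. tropicalis (n = 3 and 2, limma adjusted p = 8.57e-06), and its change of 1.69 ± 0.64 in X. laevis did not pass (adjusted p = 0.082). Both differences between species were called (adjusted p = 0.0024 and 0.000263). ENSXETG00000004083 fell 43.2-fold in X. laevis (well above background on 1 of 5 arrays at stage 40, repeats included) and had a change of 0.82 ± 0.31 in X. tropicalis (adjusted p of the difference 4.32e-08). ENSXETG00000000978 was at least 96.5-fold lower at stage 40 in X. tropicalis. The balance again depended on the scaling. Spike-in scaling gave 171 higher and 3428 lower genes in X. laevis and 375 and 144 in X. tropicalis. Quantile normalization gave 1136 and 724, and 1461 and 1260, and the normexp background 594 and 197, and 643 and 434. In X. laevis 603 genes were called without clutch B, 341 without clutch C and 626 from the 2 stages alone, and in X. tropicalis 1158 without clutch A and 730 without clutch B.

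**Figure D1:**
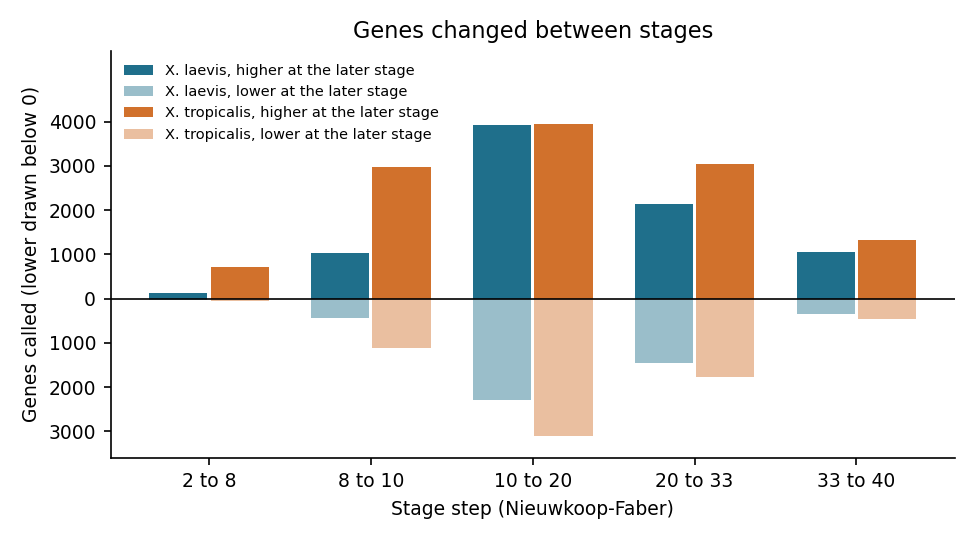
Number of genes called in each of the 5 stage steps (x axis), with genes higher at the later stage above 0 and genes lower at the later stage below 0 (y axis, number of genes, 75th-percentile scaling). The tallest bars are at the step from stage 10 to 20, 3920 higher genes in X. laevis and 3950 in X. tropicalis, and the species stand furthest apart at the step from stage 8 to 10, 1029 against 2981.

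The spike-in RNA gave a second scale for the same arrays. The 75th percentile of the array signal, relative to the spike-in signal, was lowest at stage 12 in X. laevis (-0.92 ± 0.49 log2 units, SD, n = 3) and at stage 10 in X. tropicalis (-0.73 ± 0.33, n = 3). It then rose to 0.80 ± 0.26 and 1.18 ± 0.34 at stage 33. From stage 33 to 40 it fell by 1.07 in X. laevis (SD 0.58, n = 3) and changed by -0.08 in X. tropicalis (SD 0.43, n = 2).

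**Figure D2:**
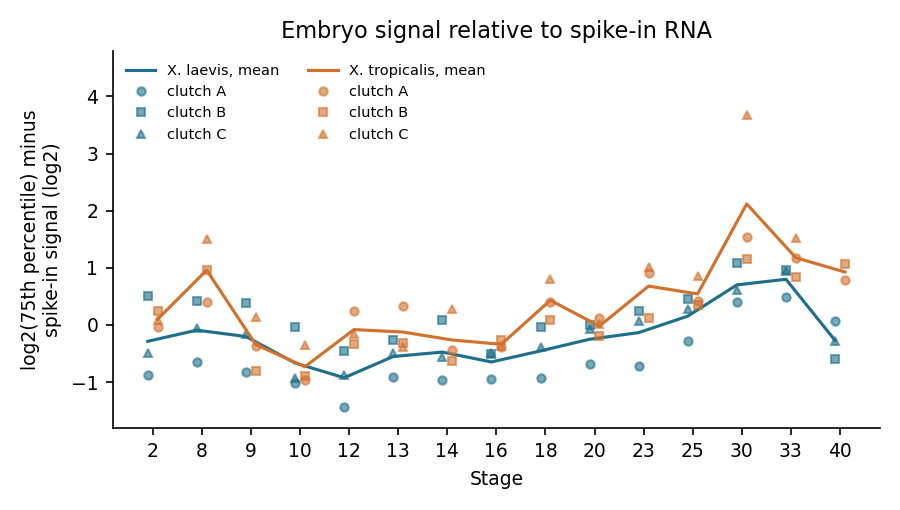
Log2 of the 75th percentile of the signal minus the log2 spike-in signal of the same array (y axis) at each stage (x axis, stages evenly spaced). Points are clutches, with repeat arrays averaged, and lines are means. The X. laevis line falls to -0.92 at stage 12 and reaches 0.80 at stage 33. One X. tropicalis array, clutch C at stage 30, stands at 3.678.

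The 2 env_control arrays of X. tropicalis, from clutches A and B, were compared with stage 10. There, limma called 1 gene, ENSXETG00000019859, which was at least 6.76-fold higher (4.29 ± 0.62 log2 units as fitted, SE, adjusted p = 0.00249, n = 2 clutches with a value in each group) and was not well above background at stage 10. It is named because it was the only call, after its value was seen. At an unadjusted p under 0.05 there were 788 genes, 5.19% of those tested. The call ended with the normexp background (adjusted p = 1), spike-in scaling (0.0786), the mean of all probes (0.676), from the 2 groups alone (1), and without clutch B (0.159) or C (0.295). With the clutch as a block 3 genes were called, without clutch A 52 and without clutch B 13, where 1 env_control array is left and assumed to vary like the other groups. Over all genes, the env_control arrays of both clutches correlated most with stage 10 (r = 0.891 and 0.916 across genes) and little less with stage 9 (0.874 and 0.89), and differed from their own clutch at stage 10 by an SD of 0.689 and 0.69 log2 units. Stage 10 of these clutches differed from stage 10 of the other clutches by 1.003 and 0.9, from its own stage 9 by 0.677 and 0.647, and from its own stage 12 by 1.374 and 1.424.

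The changes of the 2 species overlapped in every step. Of 14990 matched genes, 56 rose in both species from stage 2 to 8, where independent lists would share 5.98. From stage 8 to 10 it was 680 against 196, from stage 10 to 20 2258 against 995, from stage 20 to 33 1358 against 426 and from stage 33 to 40 428 against 88.8. For falls the numbers were 4 against 0.0967, 170 against 31.8, 1346 against 472, 683 against 167 and 97 against 10.2. The correlation of the changes across genes, which are not independent replicates, rose from 0.15 ± 0.06 (SD over 9 pairs of an X. laevis with an X. tropicalis clutch) at stages 2 to 8 to 0.491 ± 0.042 at 8 to 10, 0.608 ± 0.016 at 10 to 20 and 0.598 ± 0.019 at 20 to 33. It was 0.465 ± 0.02 at 33 to 40 (6 pairs). Between clutches of one species it was 0.304, 0.802, 0.864, 0.799 and 0.614 in X. laevis and 0.402, 0.773, 0.899, 0.872 and 0.846 in X. tropicalis in the order of the steps.

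Differences between the species in how a gene changed, tested as the interaction of species and stage, were also many. For stages 10 to 20 4457 of 14990 genes (29.7%) were called, with the change of X. laevis above that of X. tropicalis for 2424 and below it for 2033 (1875 and 1934 without clutch A of both species). In 981 of them both species were called in the same direction and the change differed in size, 1082 were called only in X. laevis and 1727 only in X. tropicalis, and 321 were called in opposite directions. For stages 8 to 10 there were 1653 (623 above and 1030 below), of which 22 were called in opposite directions, and for stages 20 to 33 1777 (621 and 1156), of which 67 were. Stages 2 to 8 had 279 (66 and 213) and stages 33 to 40 318 (119 and 199), with 0 and 6 in opposite directions. Blocking on the clutch raised these last counts to 437 and 600. Without clutch B of both species the counts at stages 2 to 8, 8 to 10, 20 to 33 and 33 to 40 were 92, 718, 960 and 50, without clutch C 93, 1030, 980 and 164, and without clutch A the last was 170. With the scaling used for these counts, the change was larger in X. tropicalis for most called genes. It was larger in X. laevis for 24.4%, 30.5%, 39%, 34% and 24.8% of them in the order of the steps. These shares are given for that scaling alone and may not hold with another. From stage 33 to 40, spike-in scaling called 3599 genes in X. laevis, 3428 of them lower, and 519 in X. tropicalis. The median change of all genes was then -0.89 log2 units in X. laevis and -0.139 in X. tropicalis. Spike-in scaling gave 2 above and 137 below for stages 2 to 8, 769 and 145 for 8 to 10, 840 and 1262 for 10 to 20, 159 and 363 for 20 to 33 and 9 and 158 for 33 to 40. The normexp background gave 43 and 127 for 2 to 8, 397 and 551 for 8 to 10, 502 and 489 for 20 to 33 and 69 and 79 for 33 to 40, and quantile normalization 375 and 397 for 33 to 40.

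Over the whole course, matched genes followed similar profiles. The median Pearson correlation between the stage profiles of a gene in the 2 species was 0.788 over 11235 genes (interquartile range 0.521 to 0.903), against 0.062 for the median of 1000 random pairings of genes and 0.092 for the highest of them. It was at least 0.8 for 5379 genes (47.9%) and below 0 for 967 (8.61%). From single clutches it was 0.716 ± 0.02 (SD, 9 clutch pairs), below the 0.882 ± 0.004 between X. laevis clutches and the 0.928 ± 0.014 between X. tropicalis clutches (3 pairs each). The stages matched closely. For 9 of the 15 X. laevis stages the most similar X. tropicalis stage had the same number, and for all 15 it was the same or a neighbouring stage. The other 6 stages, 9, 10, 14, 16, 25 and 30, matched the preceding X. tropicalis stage, for a mean shift of 0.4 stages. At stages 10 and 30 the margin over the same stage was small (r = 0.7 against 0.696 and 0.72 against 0.714). In single clutch pairs 6 to 13 stages matched the same number. Their mean shift was 0.396 ± 0.195 (SD, 9 pairs), with 8 pairs above 0 and 1 pair, clutch A with clutch A, at 0. Between clutches of one species the shift was at most 0.133 either way.

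**Figure D3:**
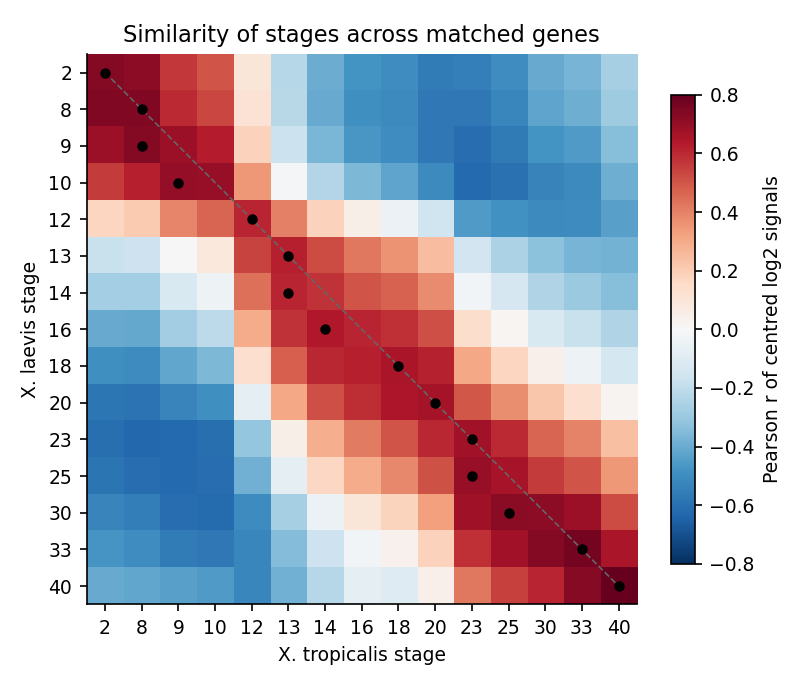
Pearson correlation across 11235 matched genes between each X. laevis stage (rows) and each X. tropicalis stage (columns), with the log2 signals of each gene centred on its mean over stages within a species. Black points mark the best X. tropicalis stage for each X. laevis stage and the dashed line marks equal stages. The points lie on the line for 9 of the 15 stages and 1 stage to its left for the other 6.

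The similarity of the species at a given stage was lowest in the early neurula. Across genes centred on their own mean, the correlation between clutches of the 2 species was 0.705 ± 0.015 (SD, 9 pairs) at stage 2, 0.549 ± 0.029 at stage 12, 0.492 ± 0.05 at stage 14, 0.721 ± 0.012 at stage 33 and 0.765 ± 0.008 (6 pairs) at stage 40. The correlation between clutches of one species was also lower at stage 14, 0.745 in X. laevis and 0.852 in X. tropicalis, than at stage 2, 0.933 and 0.952. The absolute difference between the species went the other way. Its root mean square was 1.71 log2 units at stage 2, 1.02 at stage 14 and 1.31 at stage 40.

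**Figure D4:**
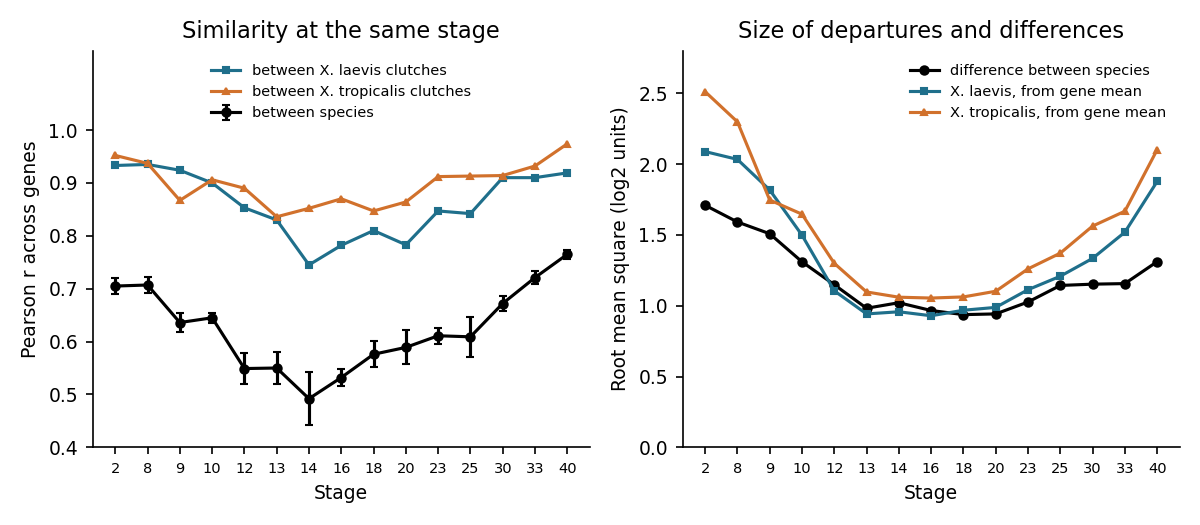
Left, Pearson correlation across genes (y axis) at each stage (x axis, stages evenly spaced), between species (mean and SD of clutch pairs) and between clutches of one species (means). Right, root mean square in log2 units of the difference between species and of the departure of each species from each gene's mean over stages. The correlation between species is lowest at stage 14, 0.492, where the root mean square difference is 1.02.

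The onsets of genes that rose after fertilization were spread unevenly over the stages, which are themselves unevenly spaced. There were 3877 matched genes that rose by at least 2 log2 units above stage 2 in both species, and their onset was taken as the first stage past the midpoint of the rise. In X. tropicalis 16.6% of them had their onset at stage 9, 19.7% at stage 12, 11.6% at stage 13 and 11.3% at stage 23. In X. laevis 4.51% had it at stage 9, 9.67% at stage 10, 21.7% at stage 12 and 13.4% at stage 13. The X. tropicalis mean at stage 9 includes the array of clutch A. That array had the highest median background (2025) and the lowest share of probes well above background (56.89%) of the X. tropicalis arrays. Onsets by stage without it were not computed. By stage 10 23.1% of the genes had started in X. tropicalis and 14.6% in X. laevis, and by stage 20 71.5% and 70.3%. The onset was at the same stage for 25.7%, later in X. laevis for 50.8% and later in X. tropicalis for 23.4%. All 9 clutch pairs, which share clutches, had more genes that were later in X. laevis. Over these pairs the mean shares were 54.4% later in X. laevis and 23.5% later in X. tropicalis. Between clutches of one species the shares differed by 29.4 percentage points for X. laevis clutches A and B and by 4.98 to 14.9 for the other 5 pairs.

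**Figure D5:**
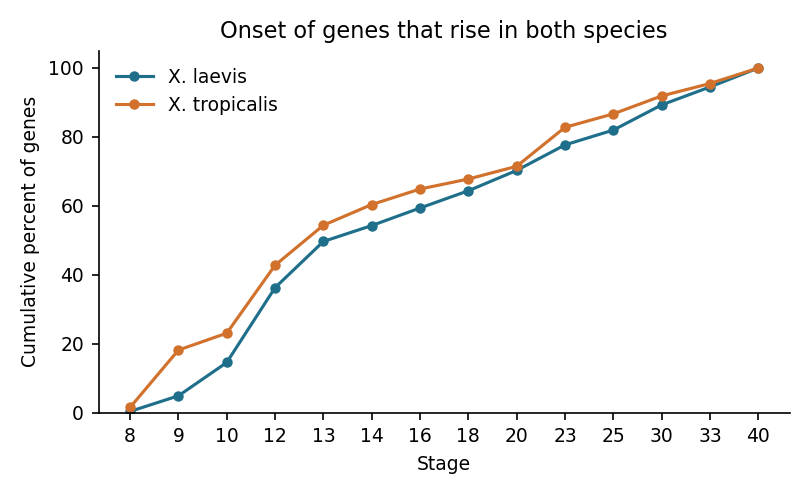
Cumulative percent of the 3877 genes that rise in both species (y axis) whose onset lies at or before each stage (x axis, stages evenly spaced), from stage means of each species. At stage 9 the X. tropicalis line stands at 18.2% and the X. laevis line at 4.93%, and at stage 20 the lines stand at 71.5% and 70.3%.

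The 5 repeated arrays were set against arrays of different clutches. Probe signals of the 2 arrays of one clutch and stage differed by an SD of 0.155 to 0.296 log2 units (median 0.215, n = 5 pairs), and signals of different clutches at the same stages by 0.541 to 0.76. The X. laevis repeats lay in the scan of their first array and the X. laevis clutches in different scans, so clutch and scan are mixed there. The X. tropicalis repeats, at stages 12 and 8, crossed scans. They differed by 0.282 and 0.296, against 0.541 and 0.61 between clutches. The labels do not say whether a repeat used the same RNA.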

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

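The tests of scaling and the centring on 3 points were chosen after the result was seen, and the other tests before.

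The change over a step differed between the species, by the interaction test, for 279 genes at stages 2 to 8, 1653 at 8 to 10, 4457 at 10 to 20, 1777 at 20 to 33 and 318 at 33 to 40. The other probes of the same genes gave the same sign for 95.2% of the called differences (8067 of 8475, 94.9% to 97.1% over the steps), which argues against probe-specific signal. A compressed signal on the X. laevis arrays would leave few larger changes in X. laevis. With the scaling used for these calls, 35.3% of the called differences had the larger change there, which argues against compression as the whole cause. A scale factor per array moves the mean change of all genes of a step alike. With each gene's spread held fixed, any such shift from -3 to 3 log2 units left at least 97.9% as many genes called (8304 against 8484 over the 5 steps, 95.3% to 100% in single steps, and 84% or more without 1 clutch). This argues against a common shift as the whole cause. Factors that differ between clutches also change the spread, which the shift did not cover, so the part of the scaling stays open. The number depended on the scaling, with 139, 914, 2102, 522 and 167 genes with spike-in scaling and 265, 1387, 4601, 2148 and 772 with quantile normalization, and the sum of homeologous copies, the rearing temperature and the separate arrays and scans of the species stay untested, so that a difference of biology is a hypothesis only.

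More genes were called from stage 8 to 10 in X. tropicalis (4098) than in X. laevis (1458). A larger spread between X. laevis clutches does not account for all of this excess. Without any p, 2.18 times as many genes changed by at least 1 log2 unit (4991 against 2293). With 1 clutch left out it was 1.78 to 2.43 times as many. The spread may account for a part, as the median SE was 0.403 log2 units in X. laevis and 0.315 in X. tropicalis. A scale factor per array does not account for all of the excess either. In X. tropicalis 2.03 times as many genes lay at least 1 log2 unit away from the median change of all genes (4644 against 2290). With 1 clutch left out it was 1.7 to 2.33 times as many. For rises from 0 the scaling may account for the excess, as spike-in scaling left 1.1 times as many rising genes (592 against 539), but not for the 1.79 times as many genes at least 1 log2 unit above the median change (2367 against 1319, and 1.63 to 2 times as many without 1 clutch). Whether X. tropicalis is further along at a given stage could not be told from the correlation of changes. The X. laevis change correlated about equally with the X. tropicalis change from stage 8 to 9 and from 8 to 12 (difference of r 0.011, SD 0.029, 9 clutch pairs), and most with that from 8 to 10 (0.491). X. laevis stage 9 was more similar to X. tropicalis stage 8 (r = 0.733) than to stage 9 (0.685). Stage 10 was about equally similar to stages 9 and 10 (0.7 and 0.696), and stage 8 to stages 8 and 2 (0.74 and 0.739). By stage 9 4.93% of the rising genes had their onset in X. laevis and 18.2% in X. tropicalis, whose stage 9 mean includes the clutch A array of high background. Whether such a lead accounts for the number of calls was not tested.

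The similarity of the species was lower at stages 12 to 14 (mean r 0.53) than at stages 2 and 33 (0.713), in all 9 clutch pairs, which share clutches. Noise between clutches does not account for all of it. The difference was -0.183 (SD 0.029), and -0.13 (SD 0.034) after division by the root of the product of the between-clutch correlations of both species. Nor does a shift of all genes by 1 stage, with -0.171 (SD 0.027) for the best of the same and neighbouring stages. Shifts in timing that differ between genes were not tested. Centring each gene on the mean of stage 2, stages 12 to 14 and stage 33 left a difference of -0.144 (SD 0.016). Smaller departures from each gene's mean at the middle stages are a candidate explanation, since the root mean square difference between the species was also smaller there (a difference of -0.382 log2 units, SD 0.062, or -0.107, SD 0.047, with the other centring). A lower conservation of these stages was not tested apart from that.

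Spike-in RNA, which the tests of genes do not use in their main scaling, changed with stage. Relative to it, the 75th percentile of the signal fell by 0.574 log2 units in X. laevis (SD 0.264, 3 of 3 clutches) and fell by 1.691 in X. tropicalis (SD 0.279, 3 of 3 clutches) from stage 8 to 10, and it rose from stage 12 to 33 by 1.724 log2 units in X. laevis (SD 0.272, 3 of 3 clutches) and by 1.257 in X. tropicalis (SD 0.374, 3 of 3 clutches).

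Other splits of the same samples were set against the real ones. With 3 clutches at each of 2 stages there are 10 splits, too few for a share under 0.05, and the real split alone, 1 of 10, reached its count in each of the 9 steps with 3 clutches at both stages (X. tropicalis from stage 33 to 40, with 2, and the species difference there were left out). The real and the highest other counts were 155 and 65, 1458 and 140, 6216 and 189, 3587 and 25, and 1398 and 41 for the steps of X. laevis in order. For X. tropicalis they were 776 and 407, 4098 and 226, 7066 and 494, and 4813 and 78. Among splits that part every clutch, as the real one does, the highest others were 0, 55, 125, 19 and 1 in X. laevis and 61, 111, 471 and 78 in X. tropicalis. For the difference between species, splits of the 6 clutches gave 1 of 10, with 279 and 8, 1653 and 2, 4457 and 2, and 1777 and 0. For variation over stages, the real grouping alone, 1 of 100 with the random ones, reached the real 12323 genes in X. laevis (highest other 358) and the real 13802 in X. tropicalis (highest other 3259). A random grouping is thus an unlikely source of the 2 counts of genes variable over stages, though no share below 1 of 100 could be reached. For the steps and the species differences, 10 splits cannot decide this. Their other splits also mix real stages or species within a group, which can lower the counts. The regroupings moved samples across clutches.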

How the results depend on the processing

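The alternatives of flagged spots kept and of 2 single arrays left out were chosen after seeing the data, and they moved no count by over 1.5 times. Of 361 values of counts, correlations and alignments under alternatives, 301 stayed within 1.5 times the reported count or within the replicate spread. In 16 of 293 counts the balance of higher and lower genes turned, 5 of them with spike-in scaling, as at stages 8 to 10 in both species, and 5 with quantile normalization. The 60 values that moved follow, and the cause was not tested unless fewer samples give it. Of 304 further values, for peak phases, onsets, correlations of changes and the alignment within 1 stage, 67 moved by more than the replicate spread. Not all of these are listed. Of 397 values for named genes, 382 kept direction and call, 15 kept the direction and lost the call, and none reversed. Some named rises and falls rest on stages where only some arrays were well above background.

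Spike-in scaling gave 34 genes for stages 2 to 8 and 3599 for 33 to 40 in X. laevis (reported 155 and 1398), 2050, 8433, 7320 and 519 for 2 to 8, 8 to 10, 20 to 33 and 33 to 40 in X. tropicalis (776, 4098, 4813 and 1776), 0 for env_control (1), and 139, 914, 2102, 522 and 167 for the species differences in order (279, 1653, 4457, 1777 and 318). It moved the median change of all genes to 0.2, -0.407, 0.817, 0.902 and -0.89 log2 units in X. laevis (reported -0.001, 0.181, 0.386, -0.139 and 0.163) and to 0.947, -1.3, 0.806, 1.208 and -0.139 in X. tropicalis (0.091, 0.371, 0.094, 0.007 and 0.122). Quantile normalization moved it to at most 0.036 and at least -0.282, and gave 2721 for X. tropicalis 33 to 40, 9 for env_control and 772 for the species difference at 33 to 40. Normexp gave 791 for X. laevis 33 to 40, 2547 and 1077 for X. tropicalis 8 to 10 and 33 to 40, 0 for env_control, and 170, 948, 991 and 148 for the species differences at 2 to 8, 8 to 10, 20 to 33 and 33 to 40.

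The replicate block on the clutch gave 252 for X. laevis 2 to 8, 3 for env_control and 437 and 600 for the species differences at 2 to 8 and 33 to 40. It changed no other count by over 1.5 times. Scans as a block gave 252, 3, 434 and 614 for these, and slides as a random block (correlation 0.401 in X. laevis, 0.232 in X. tropicalis) 254 for X. laevis 2 to 8 and 639 for the species difference at 33 to 40. First arrays alone gave 2 for env_control. Fits of the 2 groups alone gave 0 and 802 and 626 for X. laevis 2 to 8, 8 to 10 and 33 to 40, 85 for X. tropicalis 2 to 8 and 0 for env_control, with fewer samples for the spread. The median profile correlation of 0.7884 was 0.6929 by Spearman and 0.7043 over all matched genes.

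Leaving out a clutch (its letter in both species for the differences), which leaves fewer samples, gave 25 to 131 for X. laevis 2 to 8, 916 to 1417 for 8 to 10 and 341 to 1866 for 33 to 40, 366 to 840 for X. tropicalis 2 to 8 and 730 to 1456 for 33 to 40 and 1 to 52 for env_control (where a lone stage 40 or env_control array is assumed to vary like the other groups), and 92 to 263, 718 to 1286, 960 to 1410 and 50 to 170 for the species differences at 2 to 8, 8 to 10, 20 to 33 and 33 to 40. The lowest were without clutch C, C, C, B, B, C, B, B, B and B. Not run were all alternatives on gene lists, as the IDs have no names, and the normexp fit on mean signals.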

Other observations

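A peak in a neighbouring phase of the other species was found for 27.2% of the matched genes that varied in both, and one in the same phase for 54%. Of genes with their peak in the gastrula of X. laevis, 24.7% peaked in the blastula of X. tropicalis and 14.6% in its neurula. Of those with their peak in the neurula of X. laevis, 21.5% peaked in the gastrula of X. tropicalis and 11.7% at its tailbud stages, and of those with their peak at the tailbud stages 21.4% peaked in the neurula and 23% at stage 40. Between the ends of the course, 6.71% of the genes of X. laevis stage 40 peaked in the blastula of X. tropicalis, and 10.7% of those of the X. laevis blastula peaked at X. tropicalis stage 40, the phase with the most genes.

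Clutches of a species differed in the onset of rising genes. Between X. laevis clutches A and B 16% of 3809 genes started later in A and 45.3% later in B, and between A and C 23.4% and 36.4%. Between X. tropicalis clutches A and B 35.8% of 4342 genes started later in A and 20.8% later in B. With spike-in scaling 44.93% of the genes that rose in both species started later in X. laevis and 30.83% later in X. tropicalis, where the reported shares were 50.84% and 23.42%.

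The X. tropicalis array of clutch C at stage 30 had the highest 75th percentile relative to its spike-in signal, 3.678 log2 units, where the other X. tropicalis stages had means between -0.73 and 1.18.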
